A study of Mus musculus with 242 samples.

How the data were processed

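Livers of female B6C3F1 mice were measured on 242 Affymetrix Mouse430_2 arrays (biotin label, 1 colour), 1 array per mouse, after 13 weeks of exposure. The deposited values are probe set signals as linear intensity, and GCOS 1.0 is named in the submitters' processing notes. Further steps and detection calls are not in the files read here. In 240 arrays the mean after trimming 2% at each end was 500, which fits a global scaling. In 2 arrays it was not, vanadium pentoxide replicate 4 (148.4) and 1,5-naphthalenediamine replicate 2. Both were multiplied by 1 factor each to reach 500. This departs from the plan, which had set values as deposited as the main choice, and the values as deposited were run as an alternative chosen after seeing the data.

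The arrays held 45101 probe sets, of which 64 were control probe sets. Of the others, 34945 had exactly 1 gene symbol in the annotation used, and 10092 had no symbol or several and were counted but not named. For each of 18193 genes, 9010 of them with more than 1 probe set, the probe set with the highest mean over all arrays was used. Values were taken as log2 of the signal plus a pseudocount of 17.3, the median over arrays of the 20th percentile. Folds of genes near the pseudocount are therefore understated. No genes were left out by signal in the main setting.

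Groups were taken from the labels. Each treated group was compared with the control set of the same vehicle and run whose animal numbers follow the treated ones, since the labels do not state the pairing. Runs were taken from the run codes in the labels and fitted apart. Run A held 2 codes, which entered as an additive block. The control sets are named as in the titles. Set CCO3 is labelled distilled water although its titles are like those of the corn oil sets, and it was kept apart. RNA integrity numbers were lowest in run A (4.7 to 7.8), and were 8.2 to 8.9 in run B, 7.4 to 9.4 in run C and 7.1 to 9.3 in run D.

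limma 3.58.1 (R 4.3.3, with the data.table package in version 1.17.8) was fitted to all arrays of a run with 1 mean per group, followed by eBayes. All limma tests were two-sided. A gene was changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison, with a fold of at least 1.5. The ± values are the SE of the limma coefficient. For the 5 chemicals with 5 doses a linear contrast over equally spaced ranks of control and doses was tested as a trend. Control sets of 1 vehicle and run were compared with each other. The difference between 1,5-naphthalenediamine and N-(1-naphthyl)ethylenediamine dihydrochloride was tested within run C. The effect of 1,4-dichlorobenzene minus that of benzene at 100 mg/kg was tested over runs A and D together. In all there were 58 comparisons, and shared controls link those within a set.

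Gene lists were tested with limma's camera, with the correlation estimated for each list, and adjusted over 1472 tests (32 lists in 46 treated groups). The lists hold 531 distinct genes, of which 62 were not measured. A preset correlation of 0.01 was the alternative. The lists, the 12 sentinel genes, the comparisons, the rule for naming genes and the alternatives were set before the data were examined, apart from those named as chosen later. The rule named, at the highest dose of each chemical, the 8 largest rises and the 8 largest falls among changed genes with every treated array on the same side of the control mean. It also named up to 4 changed members of each list with the lowest adjusted p, and the sentinel genes in every comparison. The same genes were followed over the doses. Genes named outside it are stated as such.

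Alternatives were quantile normalisation within a run, leaving out genes whose mean was in no group above the median of the run's gene values, and pseudocounts of 4.33 and 69.3. Others were fitting the 2 groups alone, pooling control sets, leaving out the run code block or adding the Gapdh 3' to 5' ratio as a covariate in run A, and leaving out each array in turn. For trends, a linear dose scale and the dosed groups alone were tried. Alternatives chosen after seeing the data were the values as deposited, malathion without 2 arrays of low RNA integrity, control sets ACO3 and ACO4 for naphthalene, and the Gapdh ratio as a covariate in run C and for 1,4-dichlorobenzene in run D. The method was tested on simulated data, with changes added on the log2 scale. There the median size found for changes of 4-fold was between 1.98 and 2.07 (log2). Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.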

Results

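Liver RNA was profiled on 242 single-colour arrays, each from the pooled right, caudate and median lobes of 1 female B6C3F1 mouse. The mice started at 5 weeks of age and were exposed for 13 weeks to 1 of 26 chemicals or to a vehicle. The arrays formed 46 treated groups and 14 control groups, with 6 groups of 3 mice, 46 of 4 and 8 of 5. For 5 chemicals there were 5 doses, and for the other 21 a single dose. Gavage and inhalation were given 5 days a week and dosed feed 7 days a week. By the run codes in the labels the arrays fell into 4 runs, called A (54 arrays), B (36), C (18) and D (134) here. Each treated group was compared with control mice of the same vehicle and run. After scaling, every array had a trimmed mean signal of 500 (linear intensity), and the median signal per array ranged from 69.3 to 137. The number of arrays per group limits the precision.

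The series was collected to find liver transcripts whose change after 13 weeks could predict liver tumours in female mice, so each treated group was asked which transcripts differed from its controls. A gene was counted as changed at a limma adjusted p under 0.05 with a fold change of at least 1.5. Fold changes are treated over control, given with the log2 value ± its SE. A trend is given as the fitted log2 change from control to the highest dose over equally spaced dose ranks. Unless stated otherwise, every treated array lay on the same side of the control mean for a gene named as risen or fallen. Such a gene also kept its call when any single array was left out, when arrays were quantile normalised, when dim genes were left out (if it passed that filter) and at a pseudocount 4 times lower or higher. Fitting only the 2 groups compared, in place of all groups of a run, kept 114 of the 419 named calls, so most calls rest on a variance shared over the groups of a run.

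At the highest dose, limma called no gene with 8 of 26 chemicals, 1 to 20 with 7 and over 100 with 6. The 8 include naphthalene, called at lower doses, and 2 chemicals whose arrays parted 2 to 2. Malathion changed 792 genes, 1,5-naphthalenediamine 614, 2,3-benzofuran 596, methylene chloride 531, 1,4-dichlorobenzene 126 and N-(1-naphthyl)ethylenediamine dihydrochloride 117. The glutathione transferase gene Gstm3 rose with the most chemicals, 9, against 8 control sets. The transporter gene Abcc4 rose with 8 chemicals against 6 control sets, the epoxide hydrolase gene Ephx1 and the glutathione transferase gene Gsta2 each with 8 against 7, and the aldehyde oxidase gene Aox1 with 7 against 5. The glutaminyl cyclase gene Qpct fell with 8 chemicals against 6 control sets.

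**Figure D1:**
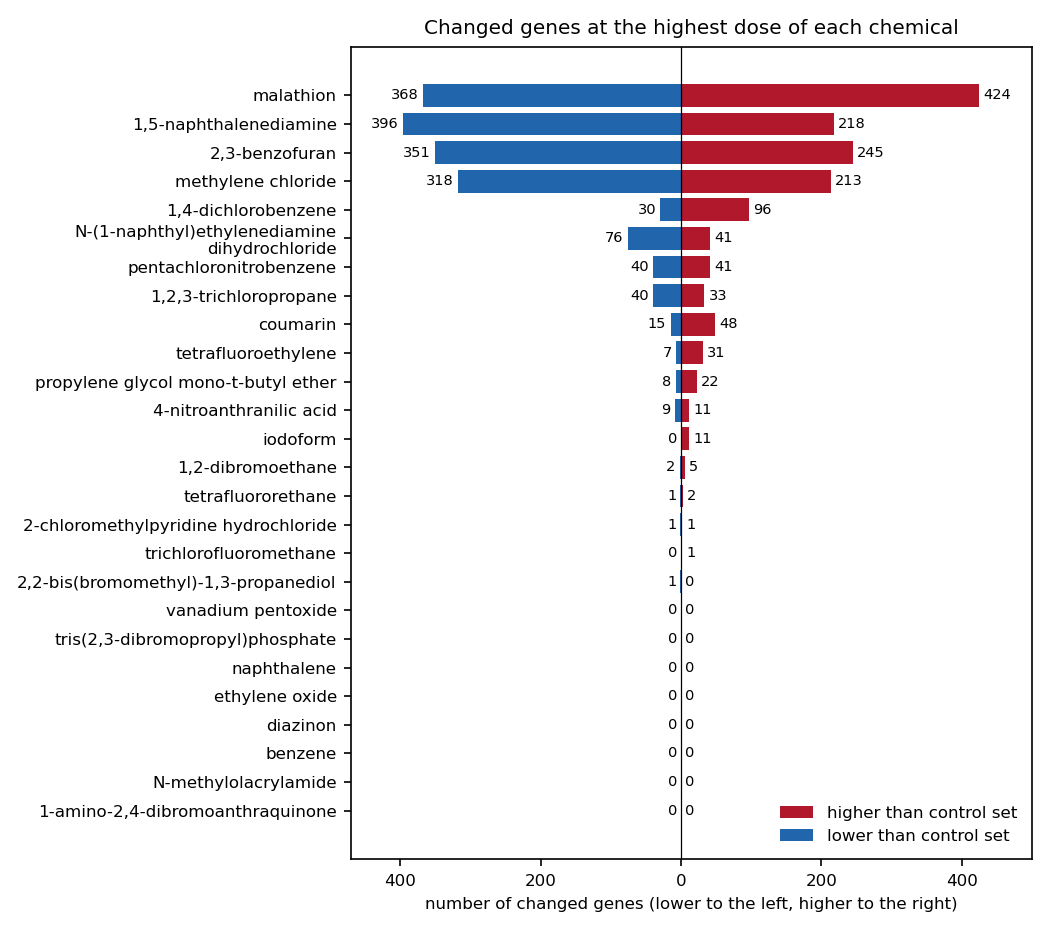
Number of genes called higher (right) and lower (left) than controls at the highest dose of each of the 26 chemicals, with 3 to 5 mice per group. Malathion has the most (424 higher, 368 lower), and 8 chemicals have none.

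Of 32 gene lists fixed before the data were examined, the NRF2 targets moved in the most groups. They were shifted upward in 19 of the 46 treated groups by camera with an estimated correlation between genes (Benjamini-Hochberg over 1472 tests). CAR and PXR targets were shifted upward in 7 groups, p53 targets in 6 and AhR targets in 2, and female-biased liver genes were shifted downward in 5. Each of the following lists passed in 1 group. Fatty acid synthesis genes and fetal and tumour markers were shifted upward with iodoform, interferon response genes upward with pentachloronitrobenzene, and bile duct markers upward with propylene glycol mono-t-butyl ether at 300 ppm. Male-biased liver genes were shifted downward with malathion, and bile acid and FXR genes and pericentral hepatocyte genes downward with methylene chloride at 4000 ppm. Each p of a list below is this camera value, and counts over the list alone are adjusted among its genes only. In all, 46 of the 1472 tests passed, and 300 passed with a preset correlation of 0.01, the 46 among them. Without dim genes 12 of the 46 no longer passed. These were p53 targets with 1,2-dibromoethane, CAR and PXR targets, AhR targets and male-biased liver genes with malathion, fatty acid synthesis genes with iodoform, AhR targets with tris(2,3-dibromopropyl)phosphate, bile acid and FXR genes and pericentral hepatocyte genes with methylene chloride at 4000 ppm, and NRF2 targets with pentachloronitrobenzene and with naphthalene at 0.5, 10 and 20 ppm. After quantile normalisation 5 of these 12 were lost too, the lists with iodoform, pentachloronitrobenzene, methylene chloride and naphthalene at 0.5 ppm. RNA integrity numbers of 15 of the 46 treated groups lay wholly above (10) or below (5) those of their controls, and Gapdh 3' to 5' ratios of 6 (1 above, 5 below).

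The other 20 lists passed in no group. Their lowest camera adjusted p over the 46 groups was PPARalpha targets 0.39, cell cycle 0.35, cholesterol synthesis 0.10, ER and amino acid stress 0.19, heat shock 0.0996, hypoxia and glycolysis 0.35, metal response 0.23, acute phase 0.10, circadian clock 0.16 and gluconeogenesis and fasting 0.16. For the remaining lists it was periportal hepatocyte 0.19, stellate and fibroblast 0.22, Kupffer and macrophage 0.14, lymphocyte 0.44, neutrophil 0.45, endothelial 0.071, erythroid 0.50, hepatocyte secreted 0.14, pancreas (adjacent tissue) 0.21 and adipose (adjacent tissue) 0.47.

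Malathion, an organophosphate insecticide given in feed at 14800 ppm (5 treated and 4 control mice), shifted the NRF2, CAR and PXR, AhR and p53 target lists upward and the list of male-biased liver genes downward. The estrogen sulfotransferase gene Sult1e1 rose 83.1-fold (log2 6.38 ± 0.56, adjusted p = 4.7e-11). The cytochrome P450 genes Cyp2c55 and Cyp2b10, both CAR and PXR targets, rose 49.0-fold (log2 5.61 ± 0.38) and 12.1-fold (log2 3.60 ± 0.50), and the efflux transporter Abcc4 rose 17.3-fold (log2 4.12 ± 0.31). Of the NRF2 targets, 22 of 26 rose and 0 fell (22 and 0 over the list alone, median log2 1.49, adjusted p = 9.1e-08), among them Gstm3 (log2 3.30 ± 0.35), Ugdh (log2 2.68 ± 0.27) and Nqo1 (log2 1.51 ± 0.23). Of the CAR and PXR targets, 7 of 18 rose and 0 fell (7 and 1 over the list alone, median log2 0.48, adjusted p = 0.022), and of the AhR targets, 3 of 8 rose and 0 fell (3 and 0 over the list alone, median log2 0.73, adjusted p = 0.027), with Cyp1a1 (log2 1.39 ± 0.26). Of the p53 targets, 8 of 28 rose and 0 fell (12 and 1 over the list alone, median log2 0.56, adjusted p = 0.0080), led by the cell cycle inhibitor Cdkn1a, which rose 11.8-fold (log2 3.56 ± 0.70, adjusted p = 6.7e-04), with Phlda3 (log2 2.39 ± 0.30), Ccng1 (log2 1.70 ± 0.15) and Aen (log2 1.32 ± 0.19).

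The shift of the male-biased liver genes with malathion did not pass without dim genes. Of these, 1 of 12 rose and 8 fell (3 and 9 over the list alone, median log2 -1.50, adjusted p = 0.022), with the uptake transporter Slco1a1 (log2 -5.53 ± 0.68), Hsd3b5 (log2 -4.47 ± 0.91) and Serpina12 (log2 -3.54 ± 0.45). The female-predominant sulfotransferase Sult3a1 fell 61.8-fold (log2 -5.95 ± 0.70, adjusted p = 6.5e-08) while Sult2a2 rose 11.8-fold (log2 3.56 ± 0.70). Pericentral genes included Glul, the glutamine synthetase gene, which fell 3.61-fold (log2 -1.85 ± 0.18, adjusted p = 9.8e-10), and the glutamate transporter Slc1a2 (log2 -1.66 ± 0.28), although for the pericentral hepatocyte list 1 of 14 rose and 4 fell (1 and 5 over the list alone, median log2 -0.12, adjusted p = 0.50). In lipid metabolism, squalene epoxidase Sqle rose 6.06-fold (log2 2.60 ± 0.44) and the acetyl-CoA carboxylase gene Acacb fell 5.56-fold (log2 -2.47 ± 0.41), although its other probe set rose (log2 0.354). For cholesterol synthesis, 8 of 19 rose and 0 fell (11 and 1 over the list alone, median log2 0.96, adjusted p = 0.35). In total 424 genes rose and 368 fell with malathion. RNA integrity numbers in this group were 4.7, 4.9, 6.2 and 6.5 with 1 not given, and without the 2 arrays under 5 the count was 653.

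Diazinon, the other organophosphate, was given at 200 ppm (4 and 4 mice) against the same control set. With limma it changed 0 genes (796 at an unadjusted p under 0.05), and 1 without control replicate 2. The doses differed and the difference between the chemicals was not tested.

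Coumarin at 200 mg/kg by gavage (4 and 4 mice) shifted the NRF2 targets upward and changed sex-predominant cytochrome P450 genes. The male-predominant fatty acid hydroxylase Cyp4a12a rose 14.0-fold (log2 3.81 ± 0.62, adjusted p = 6.2e-04) and Cyp2d9 rose 3.02-fold (log2 1.60 ± 0.30), while the female-predominant Cyp3a44 fell 7.58-fold (log2 -2.92 ± 0.44, adjusted p = 2.6e-04). Neither sex-biased list passed, and of the male-biased liver genes 3 of 12 rose and 0 fell (3 and 2 over the list alone, median log2 0.06, adjusted p = 0.65). Of the female-biased ones, 0 of 10 rose and 1 fell (0 and 4 over the list alone, median log2 -0.85, adjusted p = 0.14). Among the NRF2 targets, 9 of 26 rose and 0 fell (10 and 0 over the list alone, median log2 0.36, adjusted p = 0.0058), including Gstm3 (log2 2.73 ± 0.36), Gsta2 (log2 2.52 ± 0.44), Gsta4 (log2 1.44 ± 0.22) and Gstm4 (log2 1.44 ± 0.22). The cyclin D1 gene Ccnd1 fell 5.19-fold (log2 -2.38 ± 0.34, adjusted p = 9.4e-05). In total 48 genes rose and 15 fell, and the total was 38 and 37 without control replicates 2 and 4 and 32 without treated replicate 3.

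4-Nitroanthranilic acid at 10000 ppm in feed (4 and 4 mice) raised the fatty acid transporter Cd36 8.42-fold (log2 3.07 ± 0.54, adjusted p = 0.0032) and the carbonic anhydrase gene Car2 2.27-fold (log2 1.18 ± 0.16, adjusted p = 6.3e-05). The serpin pseudogene Serpina4-ps1 fell 10.6-fold (log2 -3.40 ± 0.53, adjusted p = 7.2e-04). The NRF2 targets were shifted upward, where 2 of 26 rose and 0 fell (10 and 0 over the list alone, median log2 0.49, adjusted p = 4.9e-04). The pancreatic elastase gene Cela2a was at 11.33 (log2 signal) in the array of replicate 4 and between 6.47 and 7.16 in the other 3 treated arrays, and for the pancreas (adjacent tissue) list 1 of 10 rose and 0 fell (3 and 1 over the list alone, median log2 1.06, adjusted p = 0.46). In total 11 genes rose and 9 fell, and the total was 11, 10 and 9 without control replicates 1, 3 and 4 and 10 without treated replicate 1.

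1,2-Dibromoethane at 62 mg/kg (4 and 4 mice) raised the prostaglandin D synthase gene Ptgds 5.12-fold (log2 2.36 ± 0.34, adjusted p = 2.0e-04) and Ephx1, the microsomal epoxide hydrolase gene, 2.23-fold (log2 1.16 ± 0.19, adjusted p = 0.0020). The NRF2 and p53 targets were shifted upward. Among the NRF2 targets, 2 of 26 rose and 0 fell (6 and 0 over the list alone, median log2 0.35, adjusted p = 0.014), and of the p53 targets, 1 of 28 rose and 0 fell (6 and 0 over the list alone, median log2 0.46, adjusted p = 0.031). Female-biased liver genes were shifted downward, where 0 of 10 rose and 1 fell (0 and 5 over the list alone, median log2 -1.01, adjusted p = 0.021). In total 5 genes rose and 2 fell, and the total was 3, 3 and 13 without control replicates 1, 2 and 3 and 4 without treated replicate 2. Quantile normalisation gave 6 higher and 1 lower.

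2-Chloromethylpyridine hydrochloride at 250 mg/kg (4 and 4 mice) changed 2 genes, with Gstm3 higher (log2 2.14 ± 0.36, adjusted p = 0.0082) and Baiap2 lower (log2 -0.99 ± 0.19, adjusted p = 0.049). Of its NRF2 targets, 1 of 26 rose and 0 fell (9 and 0 over the list alone, median log2 0.27, adjusted p = 0.039). The count was 0, 0 and 1 without treated replicates 1, 2 and 4 and 0 and 0 without control replicates 1 and 2, and after quantile normalisation it was 1 higher and 0 lower. 2,2-Bis(bromomethyl)-1,3-propanediol at 1250 ppm (5 and 4 mice) changed 1 gene, 4930470B04Rik, which was lower (log2 -1.49 ± 0.26) and is named after its value was seen, and the count was 0 and 0 without control replicates 1 and 3 and 0, 0 and 3 without treated replicates 2, 4 and 5. Limma called 0 genes with benzene at 100 mg/kg (710 at an unadjusted p under 0.05) and 0 with N-methylolacrylamide at 50 mg/kg (1105 at an unadjusted p under 0.05). The count with benzene was 2 without control replicate 3, and with N-methylolacrylamide 1 without control replicate 4. Benzene and N-methylolacrylamide were each given to 4 mice, with 4 controls.

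Iodoform at 93 mg/kg by gavage (4 and 4 mice) raised 11 genes and lowered none. The calcium-binding protein gene S100g (calbindin D9k) rose 73.6-fold (log2 6.20 ± 0.40, adjusted p = 8.3e-12) and the trypsin inhibitor gene Spink1 rose 21.9-fold (log2 4.45 ± 0.50, adjusted p = 4.3e-06). The sphingomyelinase-like gene Smpdl3b rose 11.1-fold (log2 3.48 ± 0.44), the protease inhibitor gene Slpi rose 6.33-fold (log2 2.66 ± 0.36), and the interferon-inducible Ifi27l2b rose 3.86-fold (log2 1.95 ± 0.30). The fatty acid synthesis list was shifted upward, and of its genes 0 of 17 rose and 0 fell (5 and 0 over the list alone, median log2 0.66, adjusted p = 0.043). For the fetal and tumour markers, 0 of 14 rose and 0 fell (4 and 0 over the list alone, median log2 0.37, adjusted p = 0.017). The total was 6 and 5 without control replicates 1 and 4 and 6 and 7 without treated replicates 2 and 4.

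Trichlorofluoromethane, another halomethane, was given at 3925 mg/kg (4 and 4 mice) against the same control set and changed 1 gene. The acute phase gene Saa2 was higher (log2 4.86 ± 0.83, adjusted p = 0.034), and the call was lost without any 1 of the 8 arrays, which gave a count of 0. S100g was called with iodoform and with none of the other 25 chemicals at their highest dose. The doses of the 2 halomethanes differed.

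Tetrafluoroethylene at 1250 ppm and tetrafluororethane (as spelled in the labels) at 50000 ppm were inhaled by 4 mice each, with 1 set of 4 control mice. Tetrafluoroethylene was called with 31 genes higher and 7 lower, and tetrafluororethane with 2 higher and 1 lower. Wdcp was higher with tetrafluoroethylene (log2 1.60 ± 0.25, adjusted p = 0.0057) and with tetrafluororethane (2.83-fold, adjusted p = 0.012). Its call was lost without control replicate 3 for tetrafluoroethylene, and without control replicate 2, treated replicate 3 and treated replicate 4 for tetrafluororethane. The count with tetrafluoroethylene rested on single arrays and was 7, 3, 0 and 1129 without control replicates 1, 2, 3 and 4 and 3, 20, 1 and 4 without treated replicates 1, 2, 3 and 4. After quantile normalisation it was 20 higher and 5 lower. For tetrafluororethane it was 0, 6 and 6 without control replicates 2, 3 and 4 and 23, 0 and 0 without treated replicates 2, 3 and 4, and after quantile normalisation 2 higher and 2 lower. The doses differed, and no list passed for either.

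1-Amino-2,4-dibromoanthraquinone at 20000 ppm and tris(2,3-dibromopropyl)phosphate at 1000 ppm in feed (4 mice each, 4 shared controls) changed 0 genes with limma (778 and 700 at an unadjusted p under 0.05), yet gene lists moved in both. Of the NRF2 targets, 0 of 26 rose and 0 fell (12 and 0 over the list alone, median log2 0.74, adjusted p = 9.1e-04) with the anthraquinone, and 0 of 26 rose and 0 fell (12 and 0 over the list alone, median log2 0.62, adjusted p = 0.0019) with the phosphate. Of the p53 targets, 0 of 28 rose and 0 fell (0 and 0 over the list alone, median log2 0.26, adjusted p = 0.0016) and 0 of 28 rose and 0 fell (3 and 0 over the list alone, median log2 0.32, adjusted p = 0.0012) in the same order. Of the AhR targets, 0 of 8 rose and 0 fell (4 and 0 over the list alone, median log2 0.71, adjusted p = 0.0028) with the phosphate. Within each group the arrays parted 2 to 2. The log2 signal of Cyp1a1, the P450 gene induced through AhR, was 7.60, 8.07, 14.50 and 14.60 in the arrays labelled anthraquinone replicates 1 to 4. In those labelled phosphate it was 14.33, 14.77, 9.77 and 7.91, and in the 4 controls 7.48, 8.43, 7.32 and 6.23. The count was 3 without treated replicate 1 of the anthraquinone group, and 2 without treated replicate 4 of the phosphate group.

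**Figure D2:**
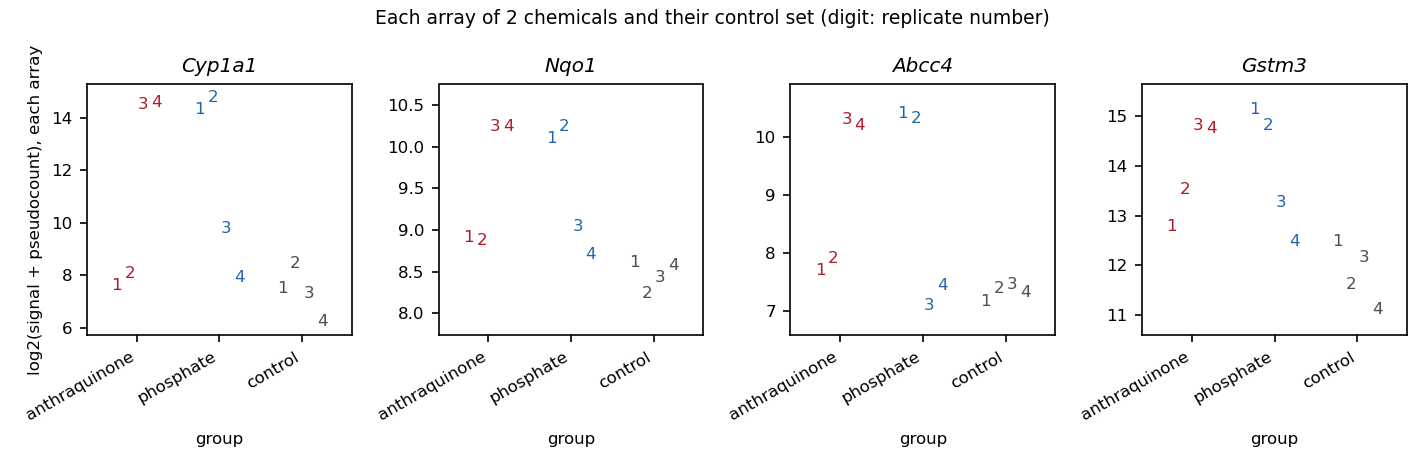
Log2 signal of 4 genes in each array of the 2 chemicals (4 mice each) and their 4 controls, 1 digit per array giving its replicate number. Cyp1a1 is at or above 14.33 in 2 arrays of each treated group and at or below 9.77 in the other 2.

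1,5-Naphthalenediamine at 2000 ppm in feed (3 treated and 3 control mice) shifted the NRF2 targets upward. Gstm3 rose 9.71-fold (log2 3.28 ± 0.29, adjusted p = 6.4e-05) and Gsta2 rose 9.23-fold (log2 3.21 ± 0.42). The actin-bundling gene Pls1 rose 8.49-fold (log2 3.09 ± 0.14, adjusted p = 7.7e-08) and the fatty acid transporter Cd36 rose 7.41-fold (log2 2.89 ± 0.26). The male-predominant genes Slco1a1 and Hsd3b5 fell 57.8-fold (log2 -5.85 ± 1.02, adjusted p = 0.0079) and 15.6-fold (log2 -3.96 ± 0.71), while the male-predominant Cyp2d9 rose 2.77-fold (log2 1.47 ± 0.25). Of the male-biased liver genes, 2 of 12 rose and 5 fell (2 and 6 over the list alone, median log2 -0.70, adjusted p = 0.79). Of the NRF2 targets, 17 of 26 rose and 0 fell (20 and 0 over the list alone, median log2 1.10, adjusted p = 0.0062), among them Ugdh (log2 2.40 ± 0.22), Aox1 (log2 2.09 ± 0.13), Gstp1 (log2 1.12 ± 0.11) and Abcc3 (log2 0.94 ± 0.13). The AhR target Cyp1a2 rose 2.37-fold (log2 1.24 ± 0.15) and Ccnd1 fell 2.85-fold (log2 -1.51 ± 0.27). In total 218 genes rose and 396 fell, and the total was 315 and 316 without control replicates 2 and 3 and 278 and 302 without treated replicates 2 and 3. The median log2 change of all genes was -0.12 as reported and 0.01 after quantile normalisation, which gave 209 higher and 149 lower. With all values as deposited, where treated replicate 2 is unscaled, the count was 708.

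N-(1-naphthyl)ethylenediamine dihydrochloride at the same dose and against the same controls (3 mice) had Sult1e1 higher (log2 2.15 ± 0.28, adjusted p = 0.011), Cyp1a2 higher (log2 1.35 ± 0.15, adjusted p = 0.0064) and the epithelial 14-3-3 gene Sfn lower (log2 -2.75 ± 0.35, adjusted p = 0.0095). RNA quality of this group lay apart from that of its controls, with integrity numbers of 7.7 to 8.1 against 8.8 to 9.1 and Gapdh 3' to 5' log2 ratios of -0.06 to 0.16 against -0.33 to -0.22. With that ratio as a covariate, an alternative chosen after the data were seen, limma called 1 gene in place of 117, and none of these 3. Their log2 values were then 1.59 ± 0.37, 1.08 ± 0.20 and -3.08 ± 0.51, and over all genes the median SE was 1.46 times as large, since the ratio also separates the groups. Among the NRF2 targets, 0 of 26 rose and 0 fell (3 and 0 over the list alone, median log2 0.13, adjusted p = 0.68). In total 41 genes rose and 76 fell, but the total was 10, 44 and 29 without treated replicates 1, 2 and 3 and 30, 26 and 28 without control replicates 1, 2 and 3. Quantile normalisation gave 27 higher and 23 lower, while the total was 359 without dim genes and 249 at the higher pseudocount.

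The 2 naphthalene amines were given at the same dose, by the same route and in the same run, and the difference between them was tested, although their RNA quality differed too (integrity 8.8 to 8.9 and 7.7 to 8.1, Gapdh ratio -0.42 to -0.05 and -0.06 to 0.16). Pls1 (log2 difference 3.03, 95% interval 2.73 to 3.34, adjusted p = 9.8e-08), Aox1 (2.18, 1.90 to 2.47, adjusted p = 1.6e-06), Ugdh (2.30, 1.84 to 2.76, adjusted p = 1.7e-04), Gstm3 (2.29, 1.66 to 2.92, adjusted p = 0.0019) and Abcc4 (1.93, 1.30 to 2.55, adjusted p = 0.0059) were higher with the diamine. Sult1e1 (log2 -2.41, -3.02 to -1.80, adjusted p = 0.0012) and the p53 target Pmaip1 (log2 -1.51 ± 0.23, adjusted p = 0.0057) were lower. The p53 target Cdkn1a was higher (log2 3.66 ± 0.67, adjusted p = 0.019), with no check of single arrays given. With the Gapdh ratio as a covariate the difference was called for 11 genes, Pls1, Aox1 and Ugdh among them, and the calls of Gstm3, Abcc4, Sult1e1 and Pmaip1 ended (log2 2.30 ± 0.44, 1.85 ± 0.43, -1.87 ± 0.36 and -1.18 ± 0.31). Without the covariate it was called for 163 genes, 89 higher and 74 lower with the diamine. The count was 100, 76 and 90 without ethylenediamine replicates 1, 2 and 3 and 81 and 67 without diamine replicates 2 and 3, and after quantile normalisation it was 92 higher and 49 lower.

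2,3-Benzofuran at 240 mg/kg by gavage (3 and 3 mice) raised Cyp4a12a 46.6-fold (log2 5.54 ± 0.53, adjusted p = 5.8e-05) and the carbonyl reductase gene Cbr3 22.6-fold (log2 4.50 ± 0.57, adjusted p = 7.1e-04). The serine synthesis gene Psat1 rose 12.1-fold (log2 3.60 ± 0.61) and the small heat shock gene Hspb1 rose 9.62-fold (log2 3.27 ± 0.21). The survivin gene Birc5 fell 7.11-fold (log2 -2.83 ± 0.46, adjusted p = 0.0044) and the female-predominant Cyp3a44 fell 4.98-fold (log2 -2.32 ± 0.37). Of the NRF2 targets, 19 of 26 rose and 0 fell (21 and 0 over the list alone, median log2 1.21, adjusted p = 0.0042), among them Abcc4 (log2 3.99 ± 0.29), Gstm3 (log2 2.85 ± 0.29), Nqo1 (log2 1.77 ± 0.30) and Gstp1 (log2 1.14 ± 0.11). The acute phase genes Saa3 and Lbp and the interferon gene Ifit3 fell, with Saa3 (log2 -1.32 ± 0.24), Lbp (log2 -0.95 ± 0.15) and Ifit3 (log2 -1.08 ± 0.13). In total 245 genes rose and 351 fell, and the total was 356, 311 and 338 without treated replicates 1, 2 and 3 and 281 and 287 without control replicates 2 and 3. The median log2 change of all genes was -0.12 as reported and 0.01 after quantile normalisation, which gave 227 higher and 214 lower.

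Pentachloronitrobenzene at 8187 ppm in feed (3 and 3 mice) raised interferon-stimulated transcripts. Ifit1 rose 5.30-fold (log2 2.41 ± 0.34, adjusted p = 0.0088) and Usp18 rose 3.74-fold (log2 1.90 ± 0.24, adjusted p = 0.0060), with Oas1a (log2 1.80 ± 0.21) and Ifit3 (log2 1.00 ± 0.13). Of the interferon response genes, 9 of 17 rose and 0 fell (12 and 0 over the list alone, median log2 1.08, adjusted p = 0.0028). Among the NRF2 targets, 6 of 26 rose and 0 fell (10 and 0 over the list alone, median log2 0.46, adjusted p = 0.034), with Gstm3 (log2 2.08 ± 0.29) and Aox1 (log2 1.08 ± 0.13). In total 41 genes rose and 40 fell, and the total was 23, 32 and 40 without treated replicates 1, 2 and 3 and 50, 49 and 35 without control replicates 1, 2 and 3. Quantile normalisation gave 44 higher and 15 lower.

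1,4-Dichlorobenzene by gavage at 5 doses (4 mice per dose, 5 controls) shifted the CAR and PXR and NRF2 targets upward at 300 to 600 mg/kg and lowered Slco1a1. Cyp2c55 rose 24.9-fold (log2 4.64 ± 0.31, adjusted p = 2.9e-23) at 600 mg/kg, Cyp2b10 rose 8.35-fold (log2 3.06 ± 0.34, adjusted p = 2.6e-11) and Abcc4 rose 8.35-fold (log2 3.06 ± 0.29), with replicate 3 above the other treated arrays. At 100, 300, 400, 500 and 600 mg/kg the log2 change of Cyp2b10 was 0.63, 2.52, 2.22, 3.09 and 3.06 (SE 0.34). Slco1a1 fell 13.7-fold (log2 -3.77 ± 0.53, adjusted p = 1.2e-07) at 600 mg/kg, with replicate 3 lying below the other treated arrays, and over the doses its log2 change was 0.11, -2.57, -1.99, -4.35 and -3.77 (SE 0.53). Of the CAR and PXR targets at 600 mg/kg, 6 of 18 rose and 0 fell (7 and 0 over the list alone, median log2 0.45, adjusted p = 2.3e-06), and both lists were shifted upward at 300, 400, 500 and 600 mg/kg. Of the NRF2 targets, 15 of 26 rose and 0 fell (16 and 1 over the list alone, median log2 0.76, adjusted p = 3.7e-17), among them Gstm3 (log2 3.03 ± 0.28), Gsta2 (log2 2.88 ± 0.37), Cbr3 (log2 2.60 ± 0.34) and Gstm4 (log2 1.80 ± 0.16). The trend over dose ranks was called for Cyp2c55 (log2 4.97 ± 0.27, adjusted p = 1.4e-30), Abcc4 (log2 3.07 ± 0.25, adjusted p = 1.4e-18) and Slco1a1 (log2 -4.52 ± 0.45, adjusted p = 9.1e-14).

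The number of changed genes with 1,4-dichlorobenzene was 13, 364, 83, 145 and 126 from the lowest to the highest dose, and the trend was called for 145 rising and 56 falling genes. At 100 mg/kg it was 1, 6 and 36 without control replicates 1, 2 and 5 and 6, 4 and 3 without treated replicates 1, 2 and 3. At 300 mg/kg it was 199 without control replicate 3 and 717, 132 and 141 without treated replicates 1, 3 and 4. At 400 mg/kg it was 49 without control replicate 2 and 32, 197 and 35 without treated replicates 2, 3 and 4. After quantile normalisation it was 12 higher and 7 lower at 100 mg/kg and 177 higher and 150 lower at 300 mg/kg. Gapdh 3' to 5' log2 ratios at 100 to 500 mg/kg (-0.59 to -0.48) lay below those of the controls (-0.41 to -0.12), and at 600 mg/kg they did not (-0.36 to -0.28). With this ratio as a covariate, chosen after the data were seen, the counts were 0, 134, 34, 99 and 128, that of the trend was 199, and the median SE at 100 to 500 mg/kg was 1.09 to 1.14 times as large. The log2 change of Slco1a1 at 400 mg/kg, no longer called, was then -1.84 ± 0.59. At 100 mg/kg the effect of 1,4-dichlorobenzene was compared with that of benzene, its unchlorinated parent ring, given at the same dose in another run. Limma called the difference for 0 genes (1171 at an unadjusted p under 0.05), and the count was 5 without corn oil control CCO2 replicate 3, 1 without 1,4-dichlorobenzene 100 mg/kg replicate 4 and 2 and 20 without benzene 100 mg/kg replicates 3 and 4.

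1,2,3-Trichloropropane by gavage at 5 doses (4 mice per dose, 5 controls) shifted the NRF2 targets upward at the highest dose. At 60 mg/kg Gsta2 rose 9.89-fold (log2 3.31 ± 0.37, adjusted p = 1.7e-10), Ptgds rose 6.33-fold (log2 2.66 ± 0.22, adjusted p = 4.4e-17) and Gstm3 rose 5.23-fold (log2 2.39 ± 0.28). The sulfotransferase Sult2a2 fell 15.4-fold (log2 -3.95 ± 0.80, adjusted p = 0.0022) and Ccnd1 fell 2.60-fold (log2 -1.38 ± 0.26), and the steroid hydroxylase gene Cyp17a1 fell 2.45-fold (log2 -1.29 ± 0.21). At 2, 6, 20, 40 and 60 mg/kg the log2 change of Gsta2 was 0.64, 0.79, 1.64, 2.40 and 3.31 (SE 0.37) and that of Sult2a2 was 0.08, 1.44, 0.22, -3.46 and -3.95 (SE 0.80). The trend was called for Gsta2 (log2 3.24 ± 0.32, adjusted p = 2.7e-13), Ptgds (log2 2.35 ± 0.19, adjusted p = 7.0e-18) and Sult2a2 (log2 -4.51 ± 0.69, adjusted p = 3.3e-06). Among NRF2 targets at 60 mg/kg, 10 of 26 rose and 0 fell (10 and 0 over the list alone, median log2 0.33, adjusted p = 9.1e-08).

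The number of changed genes with 1,2,3-trichloropropane was 5, 43, 10, 251 and 73 from the lowest to the highest dose, so it did not follow the dose, and the trend was called for 39 rising and 67 falling genes. At 2 mg/kg it was 10, 17 and 3 without control replicates 2, 3 and 4 and 9 and 10 without treated replicates 1 and 4. At 6 mg/kg it was 65 without control replicate 3. At 20 mg/kg it was 17 and 6 without control replicates 3 and 4 and 3, 3, 2 and 29 without treated replicates 1, 2, 3 and 4. At 40 mg/kg it was 161, 92 and 158 without control replicates 3, 4 and 5 and 167, 154 and 57 without treated replicates 1, 2 and 3. At 60 mg/kg it was 47 without control replicate 5 and 41 without treated replicate 3. After quantile normalisation it was 2 higher and 7 lower at 2 mg/kg, 8 higher and 29 lower at 6 mg/kg, 125 higher and 122 lower at 40 mg/kg and 46 higher and 33 lower at 60 mg/kg.

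Methylene chloride by inhalation at 5 doses (4 mice per dose, 5 controls) shifted the female-biased liver genes downward from 500 to 4000 ppm. At 4000 ppm the clock output gene Dbp rose 22.3-fold (log2 4.48 ± 0.59, adjusted p = 9.3e-09) and Ciart rose 6.39-fold (log2 2.67 ± 0.42), while the clock genes Npas2 and Arntl fell 8.33-fold (log2 -3.06 ± 0.24, adjusted p = 2.0e-18) and 4.13-fold (log2 -2.05 ± 0.24). For Arntl part of the size rests on treated replicate 4, far below the other treated arrays, and its other probe set rose (log2 0.576). The asparagine synthetase gene Asns rose 6.71-fold (log2 2.75 ± 0.35, adjusted p = 3.8e-09) and Psat1 rose 4.02-fold (log2 2.01 ± 0.46), but for the ER and amino acid stress list 2 of 20 rose and 0 fell (4 and 3 over the list alone, median log2 -0.11, adjusted p = 0.97). The female-predominant genes Sult3a1, Cyp3a16 and Cyp2b13 fell 48.7-fold (log2 -5.60 ± 0.46, adjusted p = 1.4e-17), 14.6-fold (log2 -3.87 ± 0.80) and 6.40-fold (log2 -2.68 ± 0.25). Of the female-biased liver genes, 0 of 10 rose and 5 fell (0 and 6 over the list alone, median log2 -0.66, adjusted p = 2.3e-04). Of the p53 targets, 3 of 28 rose and 0 fell (5 and 0 over the list alone, median log2 0.22, adjusted p = 0.0050), with Ccng1 (log2 1.03 ± 0.13) and Aen (log2 0.96 ± 0.14) (Aen highest in replicate 1, and higher in 2 of 3 other probe sets).

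Over 100, 500, 2000, 3000 and 4000 ppm of methylene chloride the log2 change of Dbp was -1.64, 0.14, 0.11, 2.68 and 4.48 (SE 0.59) and that of Sult3a1 was -0.83, -3.99, -5.56, -4.86 and -5.60 (SE 0.46). The trend was called for Dbp (log2 5.05 ± 0.50, adjusted p = 1.1e-13), Asns (log2 2.78 ± 0.30, adjusted p = 2.8e-12), Npas2 (log2 -2.81 ± 0.21, adjusted p = 5.7e-21) and Sult3a1 (log2 -5.96 ± 0.40, adjusted p = 1.8e-23). Of the circadian clock genes at 4000 ppm, 6 of 16 rose and 4 fell (6 and 4 over the list alone, median log2 0.56, adjusted p = 0.58). Of the pericentral hepatocyte genes, 0 of 14 rose and 2 fell (0 and 4 over the list alone, median log2 -0.32, adjusted p = 0.022), with Lgr5 (log2 -1.08 ± 0.19) and Slc1a2 (log2 -0.92 ± 0.15). The other probe set of Lgr5 stayed near 0 (log2 0.008), and 2 of 4 others of Slc1a2 fell. Of the bile acid and FXR genes, 0 of 16 rose and 2 fell (0 and 2 over the list alone, median log2 -0.22, adjusted p = 0.043). The hour at which the livers were taken is not in the labels.

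The number of changed genes with methylene chloride was 2, 133, 150, 554 and 531 from the lowest to the highest dose, and the trend was called for 258 rising and 377 falling genes. At 100 ppm it was 1, 16 and 0 without control replicates 2, 4 and 5 and 0 and 4 without treated replicates 1 and 3. At 500 ppm it was 86, 70, 315 and 47 without control replicates 1, 2, 3 and 5 and 51 without treated replicate 2. At 2000 ppm it was 76 without treated replicate 3. At 3000 ppm it was 325 without treated replicate 4.

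Propylene glycol mono-t-butyl ether by inhalation (4 mice per dose, 5 at 800 ppm, 5 controls) shifted the CAR and PXR targets upward at 800 and 1200 ppm. At 1200 ppm the pancreatic lipase-related gene Pnliprp1 rose 8.80-fold (log2 3.14 ± 0.38, adjusted p = 5.1e-09), Cyp2c55 rose 7.49-fold (log2 2.90 ± 0.31, adjusted p = 4.2e-11) and the carboxylesterase gene Ces2a rose 2.20-fold (log2 1.14 ± 0.14). Over 25, 75, 300, 800 and 1200 ppm the log2 change of Pnliprp1 was 0.21, 0.30, 0.30, 2.56 and 3.14 (SE 0.36 or 0.38). The trend was called for Pnliprp1 (log2 3.25 ± 0.32, adjusted p = 2.8e-13) and Cyp2c55 (log2 2.72 ± 0.26, adjusted p = 1.3e-13). Of the CAR and PXR targets at 1200 ppm, 4 of 18 rose and 0 fell (6 and 0 over the list alone, median log2 0.39, adjusted p = 0.0016), and at 800 ppm 3 of 18 rose and 0 fell (4 and 0 over the list alone, median log2 0.40, adjusted p = 0.0050). Of 10 genes of the pancreas, an adjacent tissue, 0 rose and 0 fell at 800 and 1200 ppm (median log2 0.29 and 0.18, adjusted p = 0.21 and 0.60). Of the bile duct markers at 300 ppm, 2 of 9 rose and 0 fell (5 and 0 over the list alone, median log2 1.11, adjusted p = 0.015). RNA integrity numbers at 300, 800 and 1200 ppm (8.9 to 9.2) lay above those of the controls (8.7 to 8.8).

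The number of changed genes with propylene glycol mono-t-butyl ether was 2, 0, 44, 6 and 30 from the lowest to the highest dose, with 942 genes at an unadjusted p under 0.05 where limma called 0. The trend was called for 37 rising and 9 falling genes, and this count was 21 and 141 without 1200 ppm replicates 1 and 2. At 25 ppm it was 11, 1, 1 and 0 without treated replicates 1, 2, 3 and 4 and 4, 4, 1 and 1 without control replicates 1, 3, 4 and 5. At 300 ppm it was 87, 10, 210 and 9 without treated replicates 1, 2, 3 and 4 and 7, 6, 2 and 78 without control replicates 2, 3, 4 and 5. At 800 ppm it was 3 and 3 without treated replicates 2 and 3. At 1200 ppm it was 14, 144 and 54 without treated replicates 1, 2 and 4 and 18 and 17 without control replicates 2 and 3. After quantile normalisation it was 0 higher and 1 lower at 25 ppm and 4 higher and 9 lower at 300 ppm.

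Naphthalene by inhalation (4 mice per dose, 5 controls) changed more genes at its low doses than at its highest. RNA integrity numbers were 9.1 to 9.3 at 0.5, 3 and 10 ppm, 8.4 to 8.7 at 20 and 30 ppm and 8.5 to 8.9 in the controls. Tkt, the transketolase gene of the pentose phosphate pathway, rose at 0.5 ppm (log2 0.86 ± 0.18, adjusted p = 0.0020) and at 3 ppm (log2 0.88 ± 0.18, adjusted p = 0.0012). The efflux transporter Abcc2 fell at 3 ppm (log2 -0.79 ± 0.19, adjusted p = 0.0047), and Gstm3 rose at 10 ppm (log2 1.21 ± 0.28, adjusted p = 0.010). The NRF2 targets were shifted upward at 0.5, 10, 20 and 30 ppm. At 30 ppm 0 of 26 rose and 0 fell (3 and 0 over the list alone, median log2 0.23, adjusted p = 0.0038). At 3 ppm, the dose with the most calls, 3 of 26 rose and 1 fell (4 and 1 over the list alone, median log2 0.19, adjusted p = 0.16). The genes of this paragraph other than Gstm3 were chosen after their values were seen.

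The number of changed genes with naphthalene was 453, 757, 125, 23 and 0 from the lowest to the highest dose, with 823 genes at an unadjusted p under 0.05 where limma called 0. At 30 ppm it was 38 with pooled air controls, 59 against ACO3 and 79 against ACO4. At 0.5 ppm it was 177 and 919 without control replicates 1 and 5 and 198 without treated replicate 2. At 3 ppm it was 288 and 1645 without control replicates 1 and 5 and 473 and 382 without treated replicates 2 and 3. At 10 ppm it was 60, 80, 77 and 246 without control replicates 1, 3, 4 and 5 and 69, 79 and 71 without treated replicates 1, 3 and 4. At 20 ppm it was 42, 15 and 14 without control replicates 1, 4 and 5 and 15 without treated replicate 3. At 30 ppm it was 1 without control replicate 1. After quantile normalisation it was 104 higher and 132 lower at 0.5 ppm, 184 higher and 281 lower at 3 ppm and 26 higher and 27 lower at 10 ppm. The trend was called for 5 rising and 12 falling genes, and this count was 31, 7, 7 and 9 without control replicates 1, 2, 4 and 5, 7, 9 and 9 without 0.5 ppm replicates 1, 2 and 3, 11 and 11 without 10 ppm replicates 3 and 4, 32, 8 and 4 without 20 ppm replicates 1, 3 and 4 and 8, 11 and 4 without 30 ppm replicates 2, 3 and 4. It was 135 on a linear dose scale and 1061 over the dosed groups alone.

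**Figure D3:**
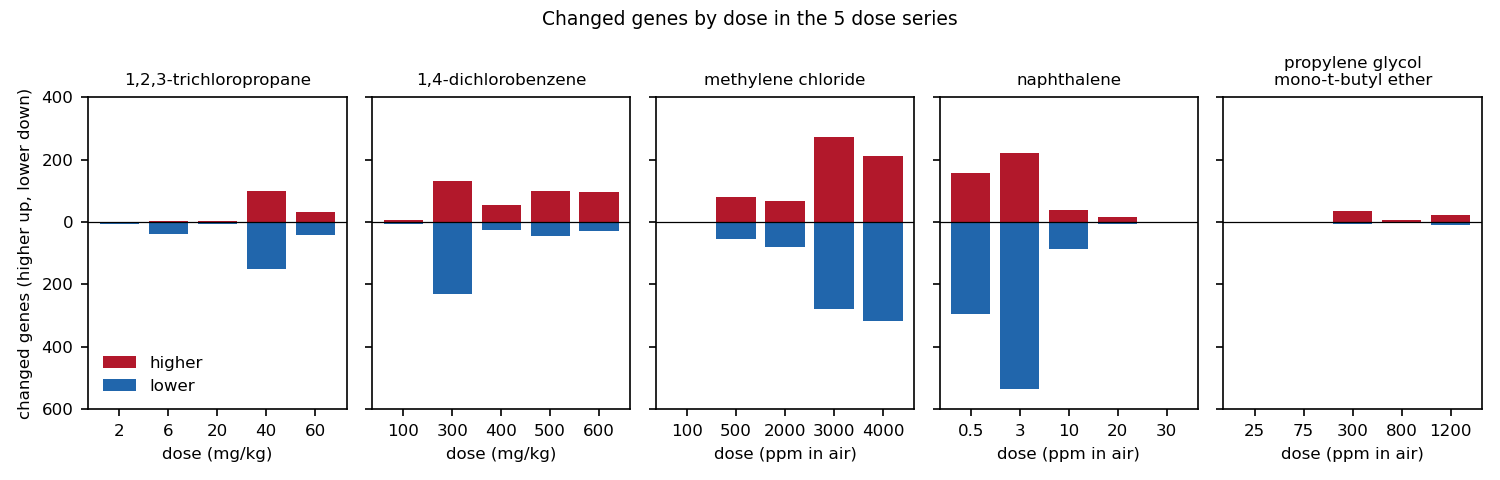
Number of genes called higher (bars up) and lower (bars down) at each of 5 doses of 5 chemicals, with doses at equally spaced ranks and 4 or 5 mice per dose. Naphthalene peaks at 3 ppm with 757 in all and has 0 at 30 ppm.

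**Figure D4:**
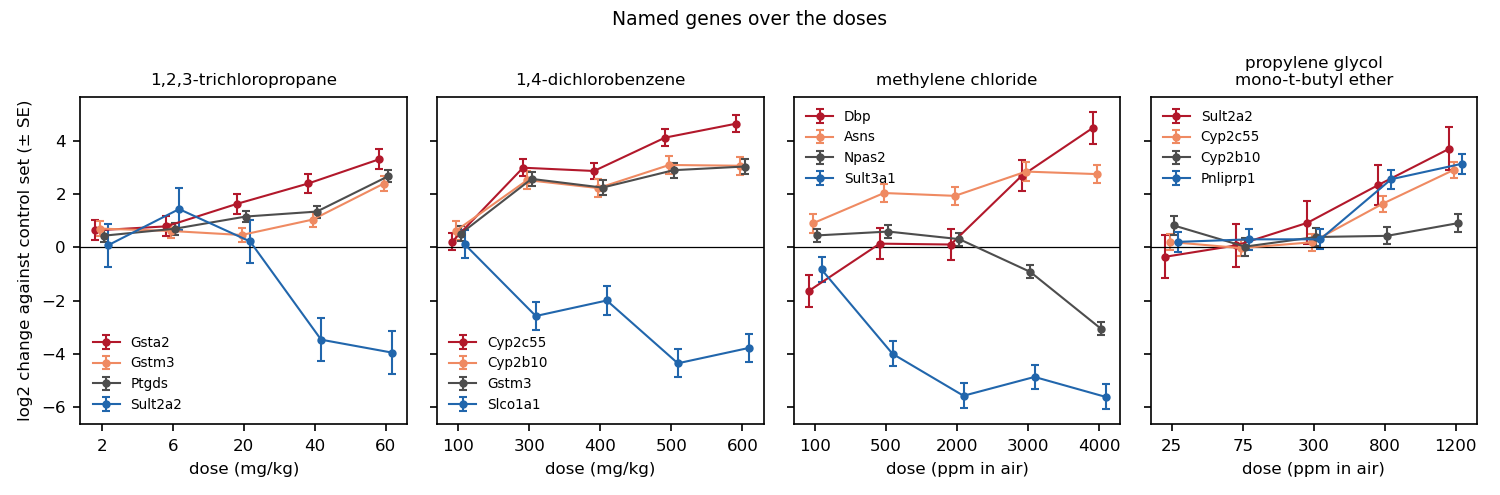
Log2 change of 4 genes for each of 4 chemicals over equally spaced dose ranks, with bars for the SE from limma and 4 or 5 mice per dose. Cyp2b10 with 1,4-dichlorobenzene and Dbp with methylene chloride are above 0 at the highest dose.

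Ethylene oxide at 100 ppm and vanadium pentoxide at 2 mg/m3 were inhaled by 4 mice each, with 5 controls each. Limma called 0 genes for either (575 and 359 at an unadjusted p under 0.05). The count with ethylene oxide was 1 without treated replicate 1, and with vanadium pentoxide 1 without treated replicate 2.

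Control sets of 1 vehicle and run were compared to see how far untreated mice differ. Of the air controls, the set used for naphthalene (ACO5) had Baz1a, a chromatin remodelling gene, below the set of propylene glycol mono-t-butyl ether at ACO3 (log2 -1.93 ± 0.30, adjusted p = 3.9e-05), and below that of methylene chloride at ACO4 (log2 -2.13 ± 0.30, adjusted p = 1.7e-06). For Sh3rf1 the values were log2 -1.74 ± 0.29, adjusted p = 1.8e-04, and log2 -1.84 ± 0.29, adjusted p = 3.9e-05. Both genes were chosen after their values were seen. ACO5 had 0 genes higher and 15 lower than ACO3, and 3 higher and 19 lower than ACO4. The count with ACO3 was 23 and 8 without ACO5 replicates 1 and 5 and 8 without ACO3 replicate 4. With ACO4 it was 36 and 13 without ACO5 replicates 1 and 4. Limma called 0 genes between ACO4 and ACO3 (908 at an unadjusted p under 0.05), between the corn oil sets CCO6 and CCO5 (2257) and between the water sets CCO3 and WCO1 (1163). The first of these was 4 without ACO4 replicate 4 and 1 without ACO3 replicate 5. The second was 1, 4, 1 and 1 without CCO6 replicates 1, 2, 3 and 5.

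**Figure D5:**
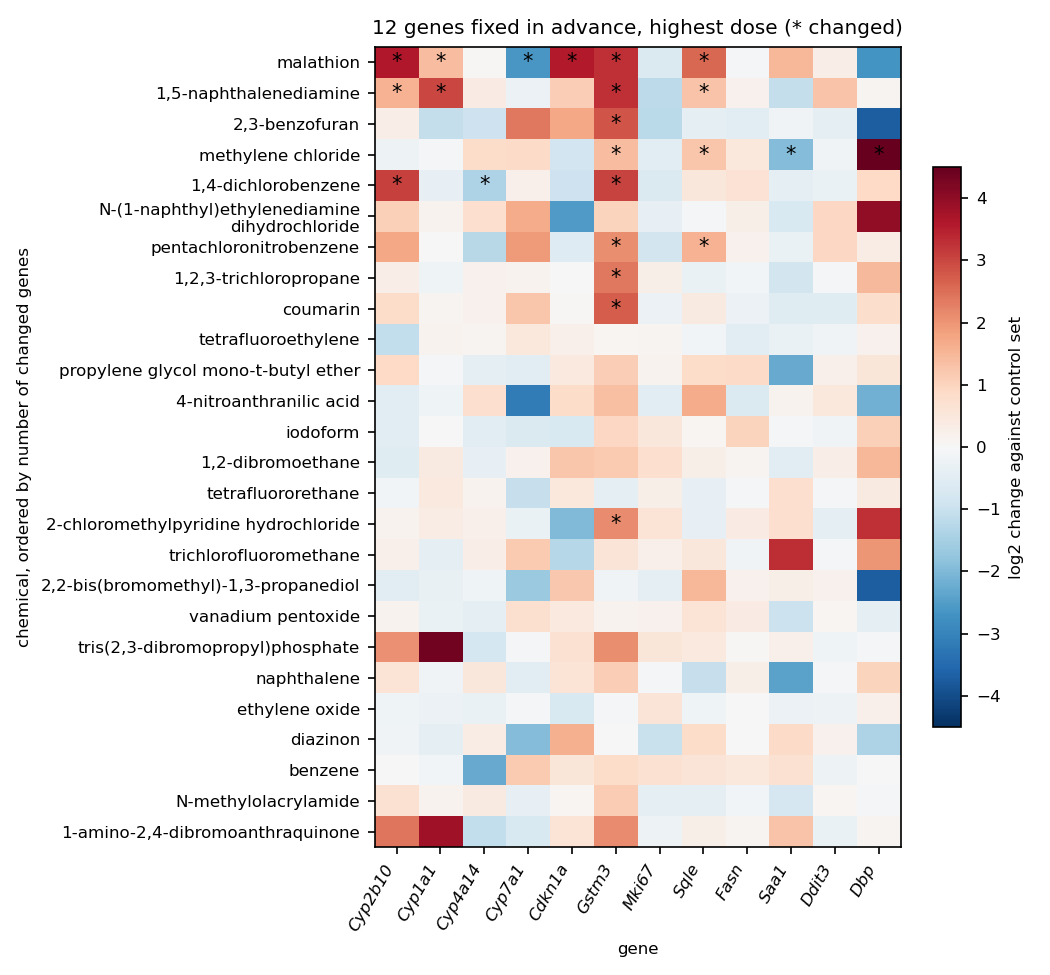
Log2 change of 12 genes fixed in advance at the highest dose of each of 26 chemicals, from blue (lower) through white to red (higher), with a star where limma called the gene. Gstm3 is called higher with 9 chemicals and Cyp2b10 with 3.

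Of the 12 sentinel genes read in every group, Mki67, Fasn and Ddit3 were called with none of the 26 chemicals at the highest dose by limma. The proliferation gene Mki67 ranged from -1.22 with 2,3-benzofuran to 0.76 with 1,2-dibromoethane.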

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

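The 3 tests of how the arrays of 1-amino-2,4-dibromoanthraquinone and tris(2,3-dibromopropyl)phosphate part, and those of malathion without its 2 arrays of low RNA integrity and of run C with the Gapdh ratio as a covariate, were chosen after those results were seen. A value lying far from the others of its group, by Dixon's 95% critical value, was found in 28 of 543 groups of gene values and in 18 of 198 groups of quality values. Chance gives about 1 in 20 groups.

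The single arrays below lay far from the others for a named gene (log2 signal). 1,2,3-trichloropropane 60 mg/kg had Actrt3 5.21 in replicate 3 (others 4.71 to 4.72). 1,4-dichlorobenzene 600 mg/kg had Abcc4 11.34 in replicate 3 (others 10.68 to 10.76) and Slco1a1 5 in replicate 3 (others 7.38 to 7.85). 4-nitroanthranilic acid 10000 ppm had Cela2a 11.33 in replicate 4 (others 6.47 to 7.16) and Lect2 11.83 in replicate 4 (others 12.46 to 12.56). Control set ACO1 had Ndufa6 13.77 in replicate 4 (others 13.97 to 14.01). Control set ACO4 had Loxl4 7.84 in replicate 4 (others 8.77 to 9.08), Meg3 9.62 in replicate 2 (others 9.23 to 9.31), Phlda3 8.01 in replicate 5 (others 7.76 to 7.8), Rsad2 8.46 in replicate 3 (others 9.36 to 9.72), Saa1 14.85 in replicate 4 (others 11.31 to 12.29) and Slc2a1 9.32 in replicate 2 (others 9.67 to 9.74). Control set FCO2 had Lpin1 14.35 in replicate 3 (others 13.65 to 13.73) and Stab2 11.17 in replicate 2 (others 11.42 to 11.45). Control set CCO2 had Sdr39u1 6.72 in replicate 2 (others 7.58 to 7.75). Control set CCO5 had Cbr3 5.38 in replicate 2 (others 6.78 to 7.02). Coumarin 200 mg/kg had Abcc4 9.59 in replicate 3 (others 8.73 to 8.86) and Gstm1 16.15 in replicate 2 (others 15.64 to 15.72). Iodoform 93 mg/kg had Csn3 6.98 in replicate 2 (others 7.45 to 7.5). Malathion 14800 ppm had Cpt1a 13.06 in replicate 5 (others 12.19 to 12.35), Cyp51 12.47 in replicate 1 (others 11.06 to 11.46) and Mup10 9.56 in replicate 1 (others 8.29 to 8.6). Methylene chloride 4000 ppm had Aen 10.01 in replicate 1 (others 9.43 to 9.5), Arntl 5.79 in replicate 4 (others 9 to 9.07), Cyp2b9 14.11 in replicate 2 (others 13.25 to 13.33), Igfbp1 10.39 in replicate 4 (others 12.27 to 12.61) and Serpina3i 8.08 in replicate 3 (others 6.89 to 6.93). Propylene glycol mono-t-butyl ether 1200 ppm had Qpct 7.77 in replicate 1 (others 8.52 to 8.66).

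The trimmed mean as deposited was 148.4 in vanadium pentoxide replicate 4 and 500 in the others of its group. The median signal was 100.6 in control CCO4 replicate 3 (others 97.2 to 97.7), 112.4 in control ACO5 replicate 1 (others 86.8 to 93.7), 107.1 in ethylene oxide 100 ppm replicate 2 (others 96.1 to 96.4), 109.6 in methylene chloride 500 ppm replicate 4 (others 100.3 to 101.4) and 94.9 in tetrafluororethane 50000 ppm replicate 2 (others 74.7 to 75.6). The Gapdh 3' to 5' log2 ratio was 0.06 in control CCO6 replicate 1 (others -0.53 to -0.40), -0.22 in 2,2-bis(bromomethyl)-1,3-propanediol 1250 ppm replicate 3 (others -0.05 to -0.03), -0.48 in 1-amino-2,4-dibromoanthraquinone 20000 ppm replicate 2 (others -0.54) and -0.40 in methylene chloride 3000 ppm replicate 1 (others -0.47 to -0.46). The RNA integrity number was 6.7 in control FCO2 replicate 4 (others 7.2), 8.7 in vanadium pentoxide 2 mg/m3 replicate 3 (others 8.6), 7.8 in coumarin 200 mg/kg replicate 2 (others 7.2), 8.5 in naphthalene 30 ppm replicate 1 (others 8.6), 8.7 in 1,2,3-trichloropropane 40 mg/kg replicate 1 (others 8.6), 9.1 in methylene chloride 4000 ppm replicate 1 (others 9.2), 8.9 in propylene glycol mono-t-butyl ether 800 ppm replicate 3 (others 9.1) and 5.7 in control WCO1 replicate 2 (others 7.2 to 7.3).

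The effects of the 2 naphthalene amines differed for 163 genes by a limma test, 105 of them with opposite signs. With the Gapdh ratio as a covariate they differed for 11, where the median SE was 1.44 times as large. Probe sets without a single gene symbol, which the comparisons of genes leave out, changed too. At the highest doses they numbered 115 with methylene chloride, 66 with malathion and 37 with 1,5-naphthalenediamine, against at most 35 between control sets. At lower doses there were 227 and 145 with naphthalene at 3 and 0.5 ppm, 170 with methylene chloride at 3000 ppm and 79 with 1,2,3-trichloropropane at 6 mg/kg.

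In the feed groups of 1-amino-2,4-dibromoanthraquinone and tris(2,3-dibromopropyl)phosphate the arrays parted 2 to 2, and array scaling was argued against, since a gap of 6.80 (log2) in Cyp1a1 stayed after quantile normalisation. RNA quality as read by the Gapdh ratio was argued against too, since the ratios of the arrays with high and low Cyp1a1 overlapped (the high array had the higher ratio in 4 of 16 pairs, where 0 or 16 would part them), and replicates 1 and 3 of the anthraquinone had the same ratio (-0.539) with Cyp1a1 at 7.60 and 14.50. A candidate explanation is that the labels of 2 arrays of each group were exchanged, since that split of the 8 arrays ranked 1 of 35 by correlation within sets minus that between sets, over 8976 genes without the AhR targets (0.22). The split with the anthraquinone 1 and 2 beside the phosphate 2 and 3 came close (0.20), and the labels as given ranked 32 (-0.11). The split was found and tested on the same arrays, so it stays a hypothesis, and no biological explanation was tested.

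Naphthalene changed more genes at 0.5 and 3 ppm than at 30 ppm. Fitting the 2 groups alone (fewer residual degrees of freedom), this did not hold at 3 ppm. The control set was argued against as the whole cause, since the count at 3 ppm against pooled air controls was 1.96 times that against its own set. Array scaling left 0.61 of the count, and for RNA integrity the median change of control set ACO4 (integrity 8.9 to 9.1) against ACO5 (8.5 to 8.9) over the 757 genes was 0.09 of that at 3 ppm (integrity 9.2, which neither set reached). Of 100 splits 5, the real one included, gave as many genes at 3 ppm, the highest (1805) moving ACO5 replicate 5 alone. A non-monotonic dose effect and a sample structure stay open, untested.

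Malathion changed 792 genes in arrays of low RNA integrity. RNA quality stays open, since known integrity lay below all controls (6.7 to 7.2) while Gapdh ratios overlapped. The ratio as a covariate left 0.85 of the count, and without the 2 lowest arrays 0.82 was left. An effect of the insecticide at this dose also stays open as a hypothesis found on the same data.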

How the results depend on the processing

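The tests with all values as deposited, without the 2 malathion arrays of an RNA integrity number under 5, of naphthalene against control sets ACO3 and ACO4, and with the Gapdh ratio as a covariate in run C and for 1,4-dichlorobenzene in run D were chosen after the data were seen. No paired analysis was possible because neither the animal numbers nor the replicate numbers pair mice across the groups compared. Short names here are the ether (propylene glycol mono-t-butyl ether), the diamine (1,5-naphthalenediamine), the ethylenediamine (N-(1-naphthyl)ethylenediamine dihydrochloride), the propanediol (2,2-bis(bromomethyl)-1,3-propanediol), the phosphate (tris(2,3-dibromopropyl)phosphate), the anthraquinone (1-amino-2,4-dibromoanthraquinone), the propane (1,2,3-trichloropropane) and the pyridine (2-chloromethylpyridine hydrochloride). A count of changed genes stayed where it moved by at most 1.5 times, and the cause of larger moves was not tested unless stated.

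Without dim genes, 45 of 58 counts stayed, and the others were 12 for 1,2-dibromoethane, 0 for the propanediol, 36 for 4-nitroanthranilic acid, 6 for the anthraquinone, 101 for tetrafluoroethylene, 359 for the ethylenediamine, 123 for pentachloronitrobenzene, 277 for the diamine minus the ethylenediamine, 12 for the propane at 2 mg/kg, 25 and 137 for 1,4-dichlorobenzene at 100 and 400 mg/kg, 26 for the ether at 300 ppm and 30 for the trend with naphthalene. After quantile normalisation, 47 of 58 counts stayed, and the others were 1 for the pyridine and N-methylolacrylamide, 25 for tetrafluoroethylene, 358 for the diamine, 50 for the ethylenediamine, 9 for the propane at 2 mg/kg, 236, 465 and 53 for naphthalene at 0.5, 3 and 10 ppm and 1 and 13 for the ether at 25 and 300 ppm. At a pseudocount 4 times lower, 43 of 46 counts stayed, and the others were 0 for the propanediol and trichlorofluoromethane and 8 for the propane at 2 mg/kg. Without a block for the run code, 5 of 9 counts stayed, and the others were 11 for 1,2-dibromoethane, 1 for the pyridine, 13 for 4-nitroanthranilic acid and 40 for coumarin. With the Gapdh 3' to 5' ratio as a covariate, 8 of 9 counts stayed, and the other was 1 for the pyridine. At a pseudocount 4 times higher, 40 of 46 counts stayed, and the others were 4 for the anthraquinone, 65 for tetrafluoroethylene, 1 for tetrafluororethane and the phosphate, 249 for the ethylenediamine and 6 for the ether at 25 ppm. With the Gapdh ratio as a covariate in run C, 3 of 5 counts stayed, and the others were 1 for the ethylenediamine and 11 for the diamine minus the ethylenediamine. With the ratio for 1,4-dichlorobenzene in run D, 3 of 6 counts stayed, and the others were 0, 134 and 34 for 1,4-dichlorobenzene at 100, 300 and 400 mg/kg. On a linear dose scale, 4 of 5 counts stayed, and the other was 135 for the trend with naphthalene. Over the dosed groups alone, 3 of 5 counts stayed, and the others were 125 for the trend with 1,4-dichlorobenzene and 1061 for the trend with naphthalene.

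Fitting the 2 groups alone, 9 of 46 counts stayed, and the others were 0 for 1,2-dibromoethane, the pyridine, the propanediol, 4-nitroanthranilic acid, coumarin, tetrafluoroethylene, tetrafluororethane, the ethylenediamine and pentachloronitrobenzene, 1 for diazinon, 2 for trichlorofluoromethane and ethylene oxide, 7 for the diamine, 81 for 2,3-benzofuran, 2, 3, 0, 0 and 7 for the propane at 2, 6, 20, 40 and 60 mg/kg, 2, 12, 6, 25 and 32 for 1,4-dichlorobenzene at 100, 300, 400, 500 and 600 mg/kg, 1, 2, 4, 20 and 34 for methylene chloride at 100, 500, 2000, 3000 and 4000 ppm, 7, 0, 2, 0 and 1 for naphthalene at 0.5, 3, 10, 20 and 30 ppm and 10, 5 and 9 for the ether at 25, 300 and 1200 ppm. This setting has fewer residual degrees of freedom. With pooled control sets, 15 of 29 counts stayed, and the others were 4 for the pyridine, 3 for N-methylolacrylamide, 1 for ethylene oxide, 10 for methylene chloride at 100 ppm, 890, 1481, 254 and 38 for naphthalene at 0.5, 3, 10 and 30 ppm, 6, 96 and 73 for the ether at 25, 300 and 1200 ppm, 84 for the propane at 40 mg/kg and 50 and 227 for 1,4-dichlorobenzene at 100 and 300 mg/kg.

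With all values as deposited, 12 of 42 counts stayed, and the others were 48 for 2,3-benzofuran, 15 for the ethylenediamine, 0 for pentachloronitrobenzene, 32 for the diamine minus the ethylenediamine, 3, 27, 4, 42 and 29 for the propane at 2, 6, 20, 40 and 60 mg/kg, 2, 117, 31, 82 and 63 for 1,4-dichlorobenzene at 100, 300, 400, 500 and 600 mg/kg, 0, 29, 43, 333 and 331 for methylene chloride at 100, 500, 2000, 3000 and 4000 ppm, 120, 287, 39 and 14 for naphthalene at 0.5, 3, 10 and 20 ppm, 15, 3 and 14 for the ether at 300, 800 and 1200 ppm, 615 for vanadium pentoxide, 60 for the trend with the propane, 3 for the trend with naphthalene and 26 for the trend with the ether. This setting leaves 1 array each of the diamine and of vanadium pentoxide unscaled, and all groups of a run share the variance. Against control set ACO3, 0 of 5 counts stayed, and the others were 947, 1586, 209, 5 and 59 for naphthalene at 0.5, 3, 10, 20 and 30 ppm. Against control set ACO4, 2 of 5 counts stayed, and the others were 1260, 10 and 79 for naphthalene at 3, 20 and 30 ppm.

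Some called changes took the other sign. With all values as deposited, Dcxr was at -0.037, Cyp51 at -0.027 and Gpam at -0.18 (log2) with the diamine, and Gstp1 was at -0.072 for the diamine minus the ethylenediamine. Against control set ACO3 the log2 changes with naphthalene were Baz1a -0.48, -0.14 and -0.12 at 0.5, 3 and 20 ppm, Arhgap32 -0.36 and -0.13 at 0.5 and 3 ppm, Sh3rf1 -0.18 and -0.34 at 0.5 and 3 ppm and Ece1 -0.0014 at 10 ppm. Against ACO4 they were Baz1a -0.68, -0.33, -0.13 and -0.31 at 0.5, 3, 10 and 20 ppm, Arhgap32 -0.36 and -0.13 at 0.5 and 3 ppm, Sh3rf1 -0.28, -0.44 and -0.082 at 0.5, 3 and 10 ppm and Ubn1 -0.069, -0.0033 and -0.12 at 0.5, 10 and 20 ppm. The sign of these changes therefore depends on the control set. Called only in the alternative, with the other sign, were Baz1a at 30 ppm (0.53, then -1.40 against ACO3 and -1.60 against ACO4) and the trend of Sh3rf1 with naphthalene (0.19, then -1.06 over the dosed groups alone).

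Leaving out 1 array at a time moved 49 of 58 counts by over 1.5 times. The ranges were 0 to 3 for the propanediol, the pyridine and the anthraquinone, 9 to 26 for 4-nitroanthranilic acid, 0 to 1 for diazinon, N-methylolacrylamide, ethylene oxide and vanadium pentoxide, 3 to 13 for 1,2-dibromoethane, 0 to 2 for benzene and the phosphate, 32 to 63 for coumarin, 5 to 12 for iodoform, 0 to 0 for trichlorofluoromethane, 0 to 1129 for tetrafluoroethylene, 0 to 23 for tetrafluororethane, 281 to 450 for 2,3-benzofuran, 10 to 44 for the ethylenediamine, 67 to 121 for the diamine minus the ethylenediamine, 23 to 50 for pentachloronitrobenzene, 278 to 514 for the diamine, 3 to 17, 33 to 65, 2 to 29, 57 to 353 and 41 to 82 for the propane at 2, 6, 20, 40 and 60 mg/kg, 0 to 4 for CCO6 minus CCO5 and ACO4 minus ACO3, 0 to 16, 47 to 315, 76 to 191 and 325 to 824 for methylene chloride at 100, 500, 2000 and 3000 ppm, 13 to 36 for ACO5 minus ACO4, 177 to 919, 288 to 1645, 60 to 246, 14 to 42 and 0 to 1 for naphthalene at 0.5, 3, 10, 20 and 30 ppm, 4 to 32 for the trend with naphthalene, 8 to 23 for ACO5 minus ACO3, 1 to 36, 132 to 717 and 32 to 197 for 1,4-dichlorobenzene at 100, 300 and 400 mg/kg, 14 to 144, 0 to 11, 2 to 210 and 3 to 7 for the ether at 1200, 25, 300 and 800 ppm, 21 to 141 for the trend with the ether and 0 to 20 for 1,4-dichlorobenzene minus benzene.

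Of 419 calls of named genes, 217 were kept without any 1 array. The number kept was 359 after quantile normalisation, 389 at the lower and 405 at the higher pseudocount, and 114 with the 2 groups alone. Without dim genes all 379 still tested were kept. With all values as deposited 144 of 279 were kept, with the Gapdh ratio as a covariate in run C 118 of 145 and with 1,4-dichlorobenzene 30 of 30, and without the 2 malathion arrays 57 of 64. Of the 46 list shifts, 41 passed after quantile normalisation and 34 without dim genes, and none took the other sign under either. Signal near the background limits low genes, since the pseudocount of 17.3 shrinks their changes. In simulated changes of 4-fold, 76% to 90% were called, and of 1.5-fold 6% to 32%.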

Other observations

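The splits below test counts of changed genes already given, and none was chosen after its result was seen. Each count was set against other splits of the same arrays into groups of the same sizes, 35 splits for 4 against 4 mice, 10 for 3 against 3, and 100 drawn splits for larger sets. Brackets hold the number of splits with as many genes, where over 1, and the highest other count. The real split is included, the 58 shares were not corrected for number, and short names are as above.

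For these counts the real split alone gave as many, but 100 splits are too few to exclude chance over 58 counts. Of 35 splits, too few for 58 counts, these were 2 (0) for the pyridine, 20 (3) for 4-nitroanthranilic acid, 63 (3) for coumarin and 11 (1) for iodoform. Of 100 splits they were 792 (223) for malathion, 251 (160) and 73 (61) for the propane at 40 and 60 mg/kg, 13 (5), 364 (269), 83 (36), 145 (84) and 126 (98) for 1,4-dichlorobenzene at 100, 300, 400, 500 and 600 mg/kg, 150 (138) and 531 (228) for methylene chloride at 2000 and 4000 ppm, 125 (69) for naphthalene at 10 ppm, 6 (3) and 30 (20) for the ether at 800 and 1200 ppm, 106 (58) for the trend with the propane, 201 (33) for the trend with 1,4-dichlorobenzene and 635 (189) for the trend with methylene chloride. Uncorrected shares under 0.05 left chance open for 5 (2 splits, 7) and 10 (4 splits, 33) for the propane at 2 and 20 mg/kg, 133 (2 splits, 323) and 554 (2 splits, 865) for methylene chloride at 500 and 3000 ppm, 453 (4 splits, 1124) and 23 (4 splits, 49) for naphthalene at 0.5 and 20 ppm, 2 (2 splits, 2) and 44 (2 splits, 64) for the ether at 25 and 300 ppm, 17 (3 splits, 369) for the trend with naphthalene, 46 (2 splits, 367) for the trend with the ether, 15 (2 splits, 16) for ACO5 minus ACO3 and 22 (4 splits, 107) for ACO5 minus ACO4.

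Other counts had no share under 0.05. Of 35 splits these were 7 (3 splits, 1197) for 1,2-dibromoethane, 38 (6 splits, 3252) for tetrafluoroethylene, 3 (15 splits, 1493) for tetrafluororethane and 1 (4 splits, 1) for trichlorofluoromethane, and of 100 splits 1 (7 splits, 10) for the propanediol, 43 (7 splits, 506) for the propane at 6 mg/kg, 2 (9 splits, 13) for methylene chloride at 100 ppm and 757 (5 splits, 1805) for naphthalene at 3 ppm. Where limma called 0 genes, all 35 or all 100 splits gave as many. The highest other count there was 1198 for benzene, 1 for diazinon, the anthraquinone and CCO3 minus WCO1, 847 for N-methylolacrylamide, 4 for the phosphate, 2 for ethylene oxide and vanadium pentoxide, 10 for naphthalene at 30 ppm, 3 for the ether at 75 ppm, 17 for ACO4 minus ACO3, 9 for CCO6 minus CCO5 and 709 for 1,4-dichlorobenzene minus benzene. With 3 against 3 mice the 10 splits are too few for a share under 0.05, and the counts were 614 (1) for the diamine, 596 (1) for 2,3-benzofuran, 117 (3) for the ethylenediamine, 81 (2) for pentachloronitrobenzene and 163 (2) for the diamine minus the ethylenediamine. Splits calling several times a real count above 0, as for 1,2-dibromoethane, tetrafluoroethylene, tetrafluororethane, the propane at 6 mg/kg and the trends with naphthalene and the ether, point to an untested structure of the samples. A treatment effect beside 1 deviating array would give the same. The highest split kept 3 of 4 treated arrays together for tetrafluoroethylene and the propane at 6 mg/kg. It kept 2 for tetrafluororethane and all 4 for naphthalene at 0.5 and 3 ppm. In run A, the only run with 2 run codes, the highest split for 1,2-dibromoethane placed arrays of the second code in both sets.

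Some labels disagree with each other. Malathion is at 14800 ppm in the dose labels, and its titles give another number. Titles of run C all carry the dose 2000, also for controls, 2,3-benzofuran (240 mg/kg) and pentachloronitrobenzene (8187 ppm). In the labels 2 animals of control set ACO1 carry the same individual number. Other probe sets of a gene were read for 167 called gene values. In 135 of them every other probe set moved in the same direction, and 185 of 314 such probe sets moved by at least 50% of the size.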
